A study of Pseudomonas aeruginosa with 2 samples.

How the data were processed

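Gene expression was measured in wild-type Pseudomonas aeruginosa PA14, a virulent laboratory strain of this Gram-negative bacterium, grown for 7 h at 37 °C in LB, a rich broth, or in LB with 10 mM adenosine, a purine nucleoside. Each medium is represented by 1 array, so the comparison has no replicates. Per the labels' protocols, cells were broken by bead beating in an RNA-stabilising solution, total RNA was purified on silica columns, and fragmented cDNA was end-labelled with biotin following the Affymetrix procedure. The array carries oligonucleotide probe sets named by PAO1 locus tags. PAO1 is the reference strain of the species, so PA14 genes that are absent from PAO1 were not part of the gene comparison, and sequence differences between the strains can lower a signal on both arrays.

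The deposited values are intensities: probe set signals on a linear scale. The MAS5 algorithm is named in the submitters' processing notes, without a version. It summarises the perfect-match and mismatch probes of a set into 1 signal and scales each array by a constant. The values bear this out, because the mean signal after removing 2% of probe sets at each end was 500.0 on the LB array and 500.5 on the adenosine array. A constant factor does not remove differences between arrays that depend on signal strength. The deposited table held no detection calls, so signal over background could not be judged probe set by probe set. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed and positions are given as PAO1 locus tags.

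The table held 5896 probe sets: 5545 for PAO1 genes, 199 for intergenic regions, 117 for sequences of other strains, 18 for tRNAs, 3 for rRNAs and 14 controls. Gene symbols were taken from the platform annotation and a RefSeq gene table of PAO1 (assembly ASM676v1) through the locus tag in the probe set name. Of the 5545 gene probe sets, 5504 had their locus tag in the RefSeq table and 1737 received a symbol; the others are called by locus tag. No probe set carried several genes in the annotation, but 96 gene probe sets had a name suffix that marks shared or non-standard probes, among them those of the duplicated phenazine operons.

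The effect of adenosine was the log2 ratio of the deposited signals, adenosine over LB, with no further scaling and no pseudocount. A gene probe set entered the comparison when at least 1 of its 2 signals reached the 25th percentile of its own array, which was 123 in LB and 89.8 with adenosine; 4429 passed and 1116 did not. A 2-fold difference was the threshold for counting. With 1 array per medium there is no test, no standard error and no p-value for any gene, and a difference between the arrays includes the variation between cultures and between hybridisations. Where a signal lay under the 25th percentile of its array, a fold is also given as "at least", computed with that signal raised to the percentile. The percentile is higher in LB than with adenosine, so "at least" is not a strict lower bound for a lower gene whose LB signal is raised. An example is fiuA, 1.10-fold lower and 1.13-fold with the floor. A probe set with both signals under the floor, such as narG, reads 1.37-fold lower by construction. This floor was chosen after seeing the data.

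Before the data were examined, 36 gene lists with 618 entries were written by PAO1 locus tag; 610 entries had a probe set. For each list the median log2 ratio of the members passing the filter was placed among the medians of 10000 random lists of the same size, drawn to match the members' mean log2 signal in 20 bins. A list was called apart at or under the 2.5th or at or over the 97.5th percentile. This describes these 2 arrays and is not a test of adenosine. Members of an operon are not independent, so the alternative background was every run of the same number of neighbouring loci. These runs were not matched on signal, so a percentile can also move for that reason. They also included the changed clusters themselves, such as the pyoverdine loci, which can draw the percentile of another list towards the middle. The genes named in the text were chosen by a rule fixed at the same time: the 10 highest and the 10 lowest log2 ratios, up to 4 members with the largest ratio in the direction of each list that stood apart, and 13 genes fixed whatever their values. Other named genes were chosen after their values were seen; they are the further members with their values in the paragraphs on each list, and the genes of the closing section.

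Alternatives fixed before the data were examined were 3 other scalings (centring on the median gene, quantile normalization, and scaling to the 3 Bacillus subtilis control probe sets that passed the filter), no filter and a filter at the array median, adding the 25th percentile of each array before the logarithm, thresholds of 1.5-fold and 3-fold, and the neighbouring-loci background. The code was tested on simulated data: 200 of 5545 genes were changed by known folds on top of noise of 0.3 (SD, log2). Of the genes simulated for the comparison of adenosine with LB, 54% of those changed 2-fold, 98% of those changed 3-fold and 100% of those changed 4-fold passed the 2-fold threshold, as did 3 of 4098 unchanged ones. Of 36 random lists, 1 was called apart. The size of the noise was assumed, because the arrays give no replicate error. Every probe set had the same noise, and the changed genes were drawn from those above the median mean signal. The random lists were made of scattered loci. These rates therefore do not carry over to weak probe sets or to lists made of operons. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.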

Results

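The effect of adenosine on the transcriptome of P. aeruginosa PA14 was examined with 2 arrays, both after 7 h of growth. The arrays were 1 for LB and 1 for LB with 10 mM adenosine. The number of arrays limits the precision: every ratio below comes from 1 array per medium, and no value carries a replicate error. The labels do not say whether cultures were pooled before hybridisation. Signals ran from 0.1 to 21118 in LB and from 0.1 to 25706 with adenosine. The 9 probe sets for yeast and Arabidopsis transcripts, which have no target in this bacterium, read at most 5.9 in LB and 18.3 with adenosine. Across the 4429 gene probe sets that passed the signal filter, log2 signals of the 2 arrays had a Pearson correlation of 0.90 (across genes, which are not independent replicates), and the log2 ratio of adenosine over LB had a median of -0.12 with quartiles at -0.45 and 0.20.

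Among the 36 gene lists fixed beforehand, purine degradation and ribose uptake had the highest median ratios of adenosine over LB, and the siderophore lists of pyoverdine and pyochelin, followed by heme uptake, the lowest. In all, 164 probe sets were at least 2-fold higher with adenosine and 346 at least 2-fold lower, so 32.2% of the changed probe sets were higher. The 10 highest ratios belonged to PA2757 (48.6-fold, at least 39.9-fold with its LB signal raised to the 25th percentile), PA1519 (28.7-fold, at least 9.12-fold), xdhA (21.1-fold), PA4880 (9.18-fold), PA1522 (9.001-fold), xdhB (8.96-fold), PA0431 (8.33-fold), PA1507 (8.29-fold), PA0440 (7.20-fold, at least 2.10-fold) and PA2172 (6.86-fold). Of these, xdhA, xdhB and PA1522 lie side by side in the purine degradation cluster.

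The 10 lowest ratios were led by pyoverdine genes. Signals with adenosine were lower by 65.4-fold for pvdL (at least 4.15-fold with the floor), 35.7-fold for pvdA (at least 26.0-fold), 28.3-fold for pvdS and 16.4-fold for pvdF (at least 9.67-fold). The others were PA2384 (19.6-fold), the sulphate transporter gene cysW (20.6-fold, at least 6.18-fold), the ferrioxamine receptor gene foxA (17.0-fold, at least 2.29-fold), PA3444 (25.5-fold, at least 2.24-fold), PA2088 (17.3-fold, at least 1.83-fold) and icmF1 of type VI secretion (15.6-fold, at least 1.66-fold). The adenosine signals of the last 4, at 12.1 or less, and of pvdL, at 5.7, lay inside the range of the yeast and Arabidopsis probe sets.

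The balance of higher and lower probe sets depended on the scaling. The share of changed probe sets that were higher was 48.7% after centring on the median gene, 47.0% after quantile normalization and 66.3% after scaling to the control probe sets. These scalings moved the median of all genes by 0.19, 0.13 and 0.40 on the log2 scale, so under the last one every log2 ratio between -0.40 and 0 turned positive. Of the 346 lower probe sets, 179 had a signal under the 25th percentile of their array, against 22 of the 164 higher ones. With all signals floored at that percentile, 247 probe sets were lower and 155 higher. The floor is higher in LB than with adenosine, so floored ratios lean towards lower. Under the main setting and its 6 alternative scalings, filters and pseudocount, 104 probe sets were at least 2-fold higher every time and 119 at least 2-fold lower every time.

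**Figure D1:**
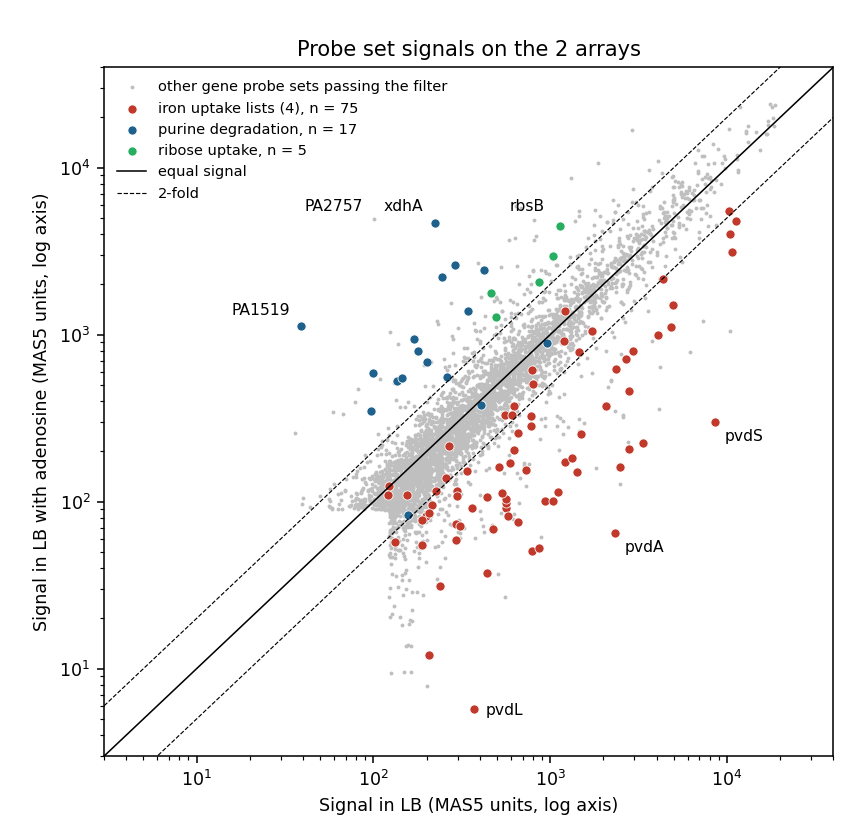
Signal of each gene probe set that passed the filter in LB (x axis) and in LB with adenosine (y axis), in MAS5 units on log axes, with 1 array per medium; the solid line marks equal signals and the dashed lines 2-fold differences. Members of the 4 iron uptake lists (red) lie mostly below the lower dashed line, with pvdS at 8517 in LB and 301 with adenosine, whereas members of the purine degradation (blue) and ribose uptake (green) lists lie mostly above the upper one.

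Iron acquisition genes were lower with adenosine across 4 separate lists, 59 of whose 75 members that passed the signal filter were at least 2-fold lower and none of which were 2-fold higher. The list for pyoverdine, the main fluorescent siderophore, had 27 of 29 members at least 2-fold lower and a median log2 ratio of -2.56 (quartiles -3.25 and -2.00), a median 5.88-fold difference that was 3.65-fold with the 25th percentile added. Its sigma factor gene pvdS, the peptide synthetase genes pvdL, pvdD (7.04-fold lower, at least 6.44-fold) and pvdJ (11.8-fold lower, at least 4.91-fold), and the ferripyoverdine receptor gene fpvA (9.52-fold lower, from 1425 to 150) were among them. The 2 members within 2-fold were fpvI and fpvR, which encode the sigma factor of the receptor gene and its antagonist, with log2 ratios of -0.75 and -0.40. Pyochelin, the second siderophore, had 12 of 14 members at least 2-fold lower (median -1.83, quartiles -2.02 and -1.39). PA4223 was 6.09-fold lower, pchF 5.56-fold, pchG 4.33-fold, pchE 4.13-fold and pchA, the salicylate synthesis gene that opens the pathway, 3.29-fold.

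Heme uptake genes were lower as well, with 8 of 11 members at least 2-fold lower (median -1.27, quartiles -2.21 and -1.06). The heme oxygenase gene hemO was 10.4-fold lower, the receptor gene phuR 7.25-fold, phuT 3.07-fold, and PA3410 6.96-fold (at least 5.32-fold). Among other iron uptake and Fur-linked genes, 12 of 21 were at least 2-fold lower (median -1.20, quartiles -1.78 and -0.72), among them PA4471 (15.4-fold), the manganese superoxide dismutase gene sodM (14.8-fold), PA4469 (13.5-fold) and foxA, for which the floor leaves at least 2.29-fold. With control scaling 5 heme uptake and 7 other iron members were at least 2-fold lower, and with the filter at the array median 6 of 13 of the latter. The list of iron storage and iron-sulphur cluster assembly had 4 of 9 members at least 2-fold lower (median -0.96), all of the isc operon: hscB (2.60-fold), hscA (2.43-fold), fdx2 (2.23-fold) and iscA (2.04-fold), which build iron-sulphur clusters; 2 of the 9 were at least 2-fold lower after median centring, 0 with control scaling and 6 after quantile normalization. The bacterioferritin genes of that list, bfrA and bfrB, had log2 ratios of -0.20 and 0.18. The gene of the iron-responsive repressor, fur, read 2378 in LB and 2452 with adenosine.

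The medians of these 5 lists lay below all 10000 signal-matched random lists. Against runs of neighbouring loci, the 4 uptake lists stayed apart (percentiles 0.125 for pyoverdine, 0.70 for pyochelin, 1.29 for heme and 0.95 for the others), and iron storage and iron-sulphur assembly did not (percentile 3.04). Those runs include the pyoverdine and pyochelin loci, so the value of 3.04 does not compare that list with unrelated loci alone.

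Purine degradation genes were higher with adenosine, 14 of 17 by at least 2-fold, with a median log2 ratio of 2.01 (quartiles 1.79 and 2.56) and a median 4.04-fold difference. The list covers the route from purine bases through xanthine, urate and allantoin to glyoxylate. The xanthine dehydrogenase genes xdhA and xdhB read 223 and 246 in LB and 4686 and 2204 with adenosine; PA1522 beside them was 9.001-fold higher. PA1519, a probable transporter gene in the same cluster, went from 39.1 to 1122. The allantoicase gene alc was 2.16-fold higher and gcl, for glyoxylate carboligase, 3.64-fold higher (at least 2.85-fold). The 3 members that were not higher lay outside this cluster. The nucleoside hydrolase gene nuh (PA0143) read 958 and 891.5, the deaminase gene PA0148 read 406 and 378.5, and PA0142 read 157 and 83.1.

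All 5 genes of the ribose uptake operon, which encodes a ribose transporter, its regulator and ribokinase, were at least 2-fold higher (median 1.52, quartiles 1.37 and 1.93). The binding protein gene rbsB was 3.93-fold higher, rbsA 3.81-fold, rbsK 2.86-fold and rbsC 2.58-fold. Purine biosynthesis genes had 0 of 14 members changed 2-fold (median -0.27) and pyrimidine biosynthesis genes 0 of 8 (median 0.24); neither list stood apart. Urease, which splits the urea that allantoin breakdown releases, had 3 of 6 members at least 2-fold lower (median -0.94): ureD (2.84-fold), ureC (2.13-fold) and ureA (2.02-fold), with ureB 1.83-fold lower; 1 of the 6 was 2-fold lower after median centring, with control scaling or with the 25th percentile added. Nitrogen assimilation genes had 1 of 9 members 2-fold lower, nirD of nitrite reduction (3.71-fold, at least 1.49-fold), and a median of 0.14; with no filter 3 of 12 were lower (median -0.22).

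Purine degradation lay above all 10000 random lists and ribose uptake at percentile 99.94; against neighbouring-loci runs they lay at percentiles 99.97 and 99.18. Urease, at percentile 0.07 among random lists, was not apart against neighbouring-loci runs (percentile 3.98).

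**Figure D2:**
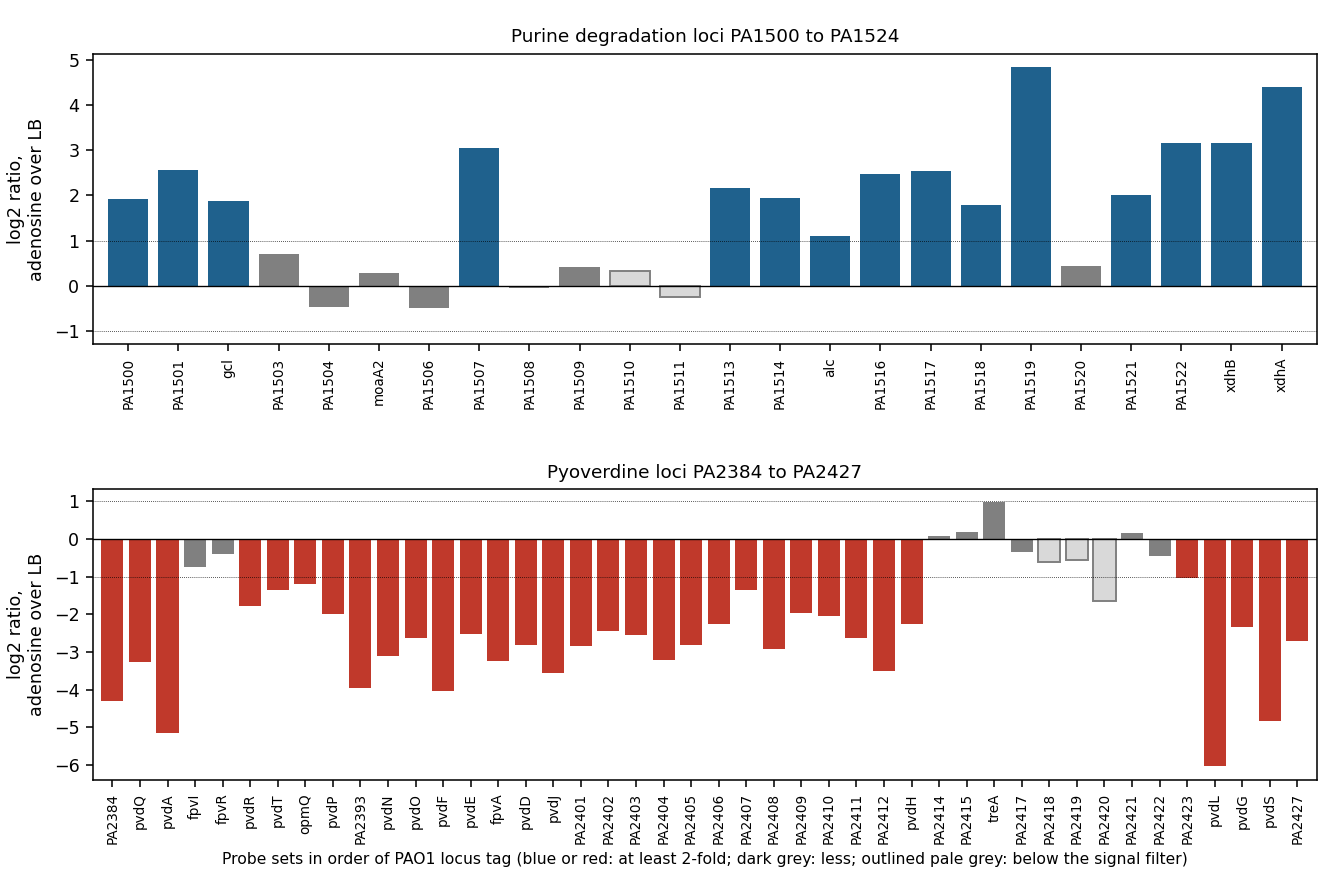
log2 ratio of adenosine over LB for each probe set in PAO1 locus order, for the purine degradation loci from PA1500 to PA1524 (upper panel) and the pyoverdine loci from PA2384 to PA2427 (lower panel); bars start at 0, coloured bars are at least 2-fold, dark grey ones less and outlined ones did not pass the signal filter. In the upper panel 15 of the 22 loci that passed the filter are at least 2-fold higher and 0 lower, and in the lower panel 33 of 41 are at least 2-fold lower and 0 higher.

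Among the lists of aerobic energy metabolism, terminal oxidases and the TCA and glyoxylate cycles stood apart and higher, whereas NADH dehydrogenase and ATP synthase did not stand apart. Terminal oxidases were not apart against neighbouring-loci runs (percentile 97.3) or with no signal filter (86.97). Terminal oxidases had 4 of 14 members at least 2-fold higher (median 0.48, quartiles -0.10 and 1.32). All 4 belong to the aa3-type cytochrome oxidase operon: coxB (4.19-fold), coxA (3.99-fold), PA0107 (3.03-fold) and coIII (2.71-fold). Genes of the first cbb3 oxidase had log2 ratios of 0.86 to 0.98, and those of the second of -0.63 to -0.06. The bo3 oxidase genes cyoA and cyoB were at -0.32 and -0.12. Of 18 TCA and glyoxylate cycle genes, 17 had a ratio above 1 and 1 reached 2-fold (median 0.50, quartiles 0.35 and 0.83): the aconitase gene acnA, 2.35-fold higher, with the succinate dehydrogenase genes sdhA, sdhC and sdhD at 1.97, 1.92 and 1.91-fold. After median centring 7 oxidase and 5 TCA genes reached 2-fold, and with control scaling 7 of each. NADH dehydrogenase and ATP synthase had 0 of 22 members changed 2-fold (median 0.06, percentile 52.5).

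Of the anaerobic lists, denitrification had 1 of 14 members 2-fold lower, nosZ, which reduces nitrous oxide (2.73-fold, at least 1.56-fold; list median -0.41). The count was 0 after quantile normalization, with the filter at the array median or with the 25th percentile added, and 8 of 29 with no signal filter (median -0.52). The nitrite reductase gene nirS read 327.5 and 262. The arginine deiminase pathway had 0 of 4 changed 2-fold (median 0.37); neither list stood apart. The oxygen-responsive regulator gene anr was 1.54-fold higher. Branched-chain amino acid degradation had 1 of 10 members 2-fold higher, the regulator gene liuR (median 0.33), at percentile 95.6; after quantile normalization the list was apart and higher (percentile 98.0). The TCA list lay at percentile 99.95 among random lists and 97.9 against neighbouring-loci runs; terminal oxidases lay at 99.98 among random lists.

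Of the quorum sensing, secretion and motility lists that stood apart, Las and Rhl, phenazine, type III and type VI secretion genes had medians below 0, and type II secretion and flagellum genes medians above 0. Against neighbouring-loci runs type III (percentile 1.73) and type VI secretion (2.45) stayed apart, whereas Las and Rhl (10.9), phenazine (9.12), type II secretion (96.1) and flagellum (96.3) did not. Those runs are not matched on signal. Signal-matched random lists had a median of -0.32 for type VI and -0.16 for type III, against -0.12 for all genes passing the filter. The runs therefore lean towards a lower call, mainly for type VI. Of 24 Las and Rhl genes, 4 were at least 2-fold lower (median -0.36, quartiles -0.83 and 0.12), all in the operon for alkaline protease and its type I secretion machinery: aprF (5.47-fold), aprE (4.33-fold), aprD (3.89-fold) and aprA (2.06-fold). The regulator genes lasR and rhlR had log2 ratios of 0.12 and 0.29, and the elastase gene lasB 0.37. Quinolone signalling genes had 0 of 14 members changed 2-fold (median -0.09), with the regulator gene mvfR at -0.65. Phenazine synthesis genes, for pyocyanin and related pigments, had a median of -0.50 over 10 members, with phzS 1.96-fold, phzG2 1.83-fold, phzA1 1.78-fold and phzF2 1.75-fold lower. In that list phzM was 2.29-fold higher. Probe sets of the phz operons are shared between near-identical copies, so the copies cannot be separated.

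Type III secretion, which injects toxins into host cells, had a ratio below 1 for 35 of 35 members and 7 at least 2-fold lower (median -0.63, quartiles -0.90 and -0.37): among them pscU (2.60-fold, at least 2.07-fold), PA1711 (2.51-fold, at least 2.38-fold), pscT (2.23-fold, at least 1.47-fold) and pcrH (2.19-fold). The number at least 2-fold lower was 2 after median centring, 1 after quantile normalization or with the 25th percentile added, and 0 with control scaling, under which 24 of the 35 had a ratio below 1 (median -0.23). In the H1 type VI secretion cluster 5 of 9 members were at least 2-fold lower (median -1.04), among them hcp1 (2.61-fold, at least 2.37-fold), pppA (2.10-fold, at least 1.89-fold) and clpV1 (2.08-fold, at least 2.07-fold); 9 further members did not pass the signal filter. That number was 2 after median centring or quantile normalization (median -0.63 after the latter) and 1 with control scaling or with the 25th percentile added, 11 of 18 were lower with no filter, and too few members passed the filter at the array median for a value. Type II secretion had 0 of 11 members changed 2-fold (median 0.37; xcpW 1.56-fold, xcpR 1.43-fold, xcpT 1.40-fold and xcpV 1.40-fold higher). Flagellum genes had 0 of 36 changed 2-fold (median 0.19; fliE 1.63-fold, fliC 1.59-fold, flhF 1.502-fold and fleS 1.49-fold higher).

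Among random lists, Las and Rhl lay at percentile 0.01, phenazine at 0.12, type III secretion at 0, H1 type VI secretion at 0.34, type II secretion at 99 and flagellum at 99.03. The flagellum list was also not apart after quantile normalization (97.0) or with the filter at the array median (96.2).

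Ribosomal protein genes had 0 of 53 members changed 2-fold and a median of -0.04 (quartiles -0.18 and 0.20), against 0.14 for random lists of the same high signal. The members with the lowest ratios were rplL (1.75-fold), rplS (1.68-fold), rplQ (1.59-fold) and rpsM (1.53-fold). Heat shock proteins and proteases had 0 of 13 changed 2-fold (median -0.24), with the protease genes hslV and hslU 1.85-fold and 1.68-fold lower, clpB 1.30-fold and ibpA 1.27-fold. Both lists were apart among random lists (percentiles 1.12 and 1.61) but not against neighbouring-loci runs (72.4 and 28.9), which are not matched on signal. Heat shock was also not apart after quantile normalization (percentile 3.33). Their medians turned positive under other scalings, to 0.14 and 0.36 for ribosomal proteins after median centring and control scaling, and to 0.16 for heat shock under the latter. The Las and Rhl median turned to 0.047 under control scaling.

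The remaining lists did not stand apart. The 6 reference housekeeping genes had 0 members changed 2-fold and a median of -0.03. Oxidative stress defence had 1 of 10 members higher, the catalase gene katA (2.30-fold), and 1 lower, katB (2.62-fold, at least 1.61-fold), with a median of -0.27. Zinc starvation had 2 of 7 lower (median -0.29), phosphate starvation 1 of 8 lower (median -0.07), alginate synthesis 2 of 7 lower (median -0.72, percentile 4.97) and Pel polysaccharide 1 of 4 lower (median -0.32). Lower members numbered 1 for zinc and 0 for phosphate and alginate after quantile normalization, 0, 0 and 1 with control scaling, and 1, 0 and 0 with the 25th percentile added; after median centring 1 zinc and 1 alginate member were lower, and with no filter 3 of 13 phosphate and 3 of 7 Pel members. The katB call was kept after median centring and with no filter. It was lost after quantile normalization, with control scaling, with the filter at the array median and with the 25th percentile added. Type IV pili (0 of 18 changed, median -0.27), DNA damage response (0 of 7, median -0.24), multidrug efflux pumps (0 of 7, median -0.22) and the PAO1 pyocin region (0 of 28, median -0.18) held no member changed 2-fold under the main setting. With no filter 2 of 26 pili members were higher, and 1 of 8 DNA damage and 2 of 11 efflux members lower. The pyocin region then had 1 of 37 higher and 4 lower. After quantile normalization or with control scaling 1 pili member was higher.

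**Figure D3:**
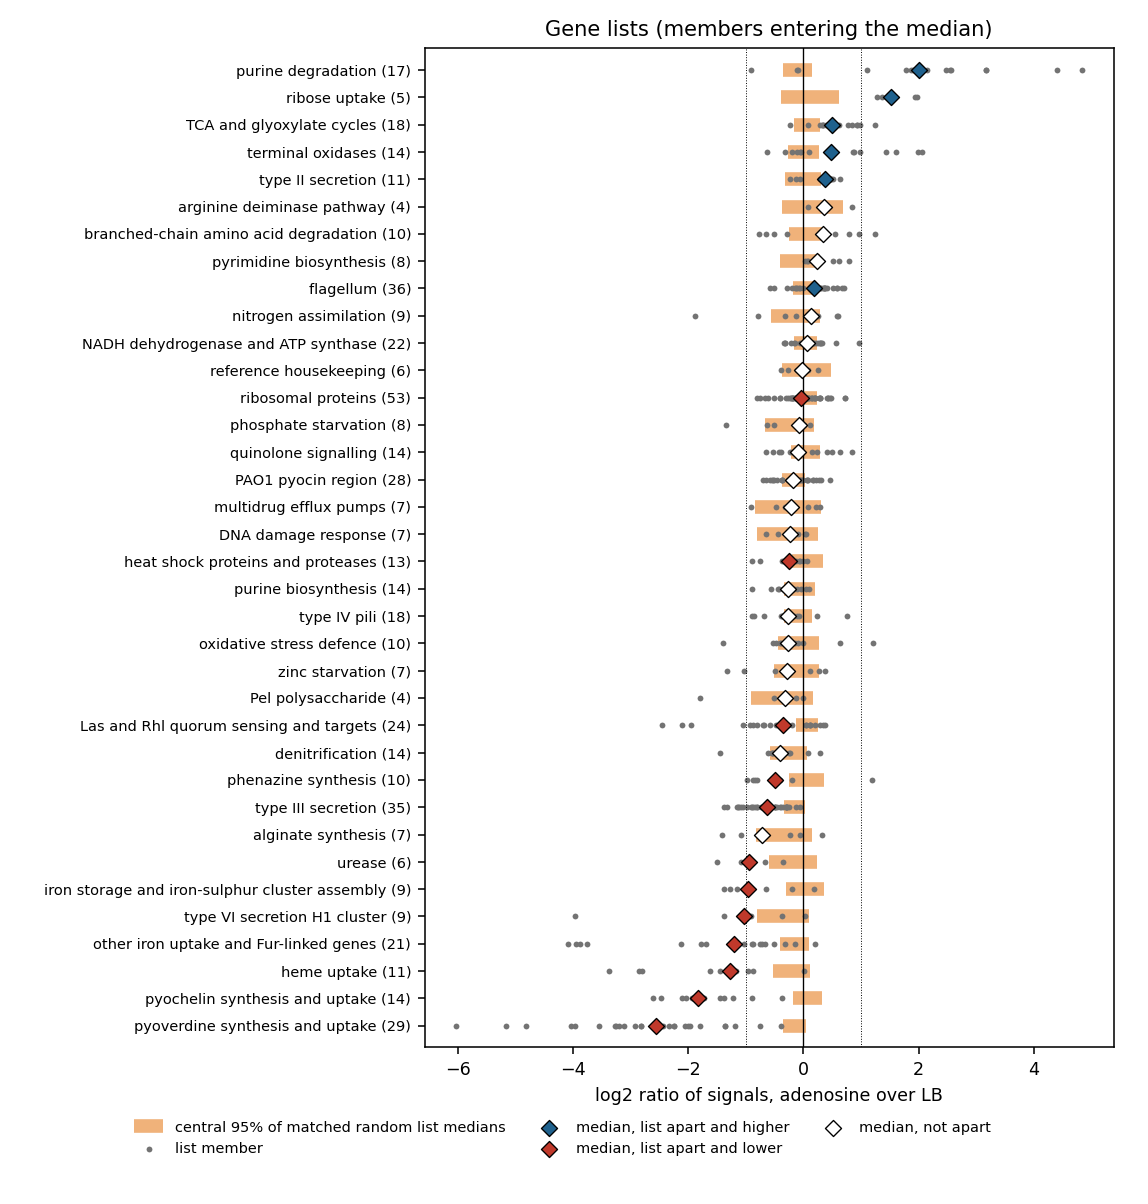
log2 ratio of adenosine over LB for the members (grey points) and the median (diamonds) of each of the 36 gene lists, with the number of members that passed the signal filter in parentheses; orange bars span the central 95% of the medians of 10000 signal-matched random lists, and dotted lines mark 2-fold. Blue and red diamonds are the 6 lists that were apart and higher and the 12 that were apart and lower, from pyoverdine at -2.56 to purine degradation at 2.01.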

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

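With 1 array per medium, neither a search for outlying samples nor a comparison of effects between groups was possible. Probe sets outside the gene comparison were checked for signals at least 2-fold above the LB array, among the 65 intergenic, 18 tRNA, 3 rRNA and 10 other-strain probe sets that passed the signal filter. The cysteine tRNA probe set was 4.12-fold higher with adenosine (397 to 1636). The glycine tRNA probe set was 2.17-fold higher (455.6 to 989). Among the intergenic probe sets, 2 were higher, 1 by 2.67-fold (107 to 286; at least 2.32-fold with the floor) and 1 by 2.07-fold (153 to 317). In the other direction, 4 intergenic probe sets, the asparagine tRNA probe set (2.12-fold) and 1 of another strain were at least 2-fold lower before any floor. No explanation was tested for these values.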

How the results depend on the processing

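The count of higher probe sets was 164 and moved to 374 with control scaling, 385 at 1.5-fold and 61 at 3-fold. The count of lower probe sets was 346 and moved to 227 after quantile normalization, 190 with control scaling, 671 with no filter, 187 with the filter at the array median, 207 with the 25th percentile added, 809 at 1.5-fold and 162 at 3-fold. The other settings left both counts within 1.5 times, including the floor at the 25th percentile, which was chosen after seeing the data. The number of gene lists apart was 18 and ranged from 16 to 18 over the other scalings, filters and the pseudocount. It was 9 against runs of neighbouring loci. That background carries the correlation within operons by construction but is not matched on signal. It also includes the changed clusters themselves, and each run is 1 stretch whereas some lists are scattered over several operons. The fall to 9 therefore cannot be put down to any 1 of these differences. Pyoverdine (median -2.56 to -1.87), pyochelin (-1.95 to -1.42), purine degradation (1.55 to 2.42) and ribose uptake (1.40 to 1.92) stayed apart in the same direction under all 7 alternatives. Of the 18 lists apart, 3 had a median that changed sign: Las and Rhl genes (0.047, control scaling), heat shock proteins (0.16, control scaling) and ribosomal proteins (0.14, median-centred; 0.36, control scaling), each by the shift the scaling adds. Of the 18 lists not apart, 12 changed sign under at least 1 alternative, all but nitrogen assimilation (no filter) under control scaling, whose constant shift sets the sign, and branched-chain amino acid degradation became apart after quantile normalization. With the filter at the array median too few members of the type VI, Pel and alginate lists were left for a value. Some lists with 0 members changed 2-fold gained higher members. With control scaling quinolone, pyrimidine, flagellum and ribosomal protein genes had 2 each. Type II secretion, arginine deiminase, and NADH dehydrogenase and ATP synthase genes then had 1 each. After median centring 1 quinolone, 1 arginine deiminase and 1 NADH dehydrogenase or ATP synthase gene was 2-fold higher. Of 93 named genes, none called at 2-fold changed sign in 548 recomputations, and 26 values moved by more than 0.48, the robust SD of all log2 ratios. Most of these outcomes were fixed in advance. Changing the filter leaves a log2 ratio as it is. Median centring and control scaling add constants of 0.19 and 0.40, too small to reverse a 2-fold call or to pass 0.48. Only quantile normalization and the added 25th percentile could move a value that far. No paired analysis was possible because each medium has 1 array, and for the same reason no replicate could be left out. Weak signals limit the lower calls, since 179 of them had a signal under the 25th percentile and the table holds no detection calls.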

Other observations

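Changed genes outside the fixed lists also lay in neighbouring groups, all singled out after their values were seen. No list or enrichment test covers them. The run from cysA to PA0284 (5 of 5 loci lower, median log2 ratio -3.02, or -2.78 with signals floored at the 25th percentile) included the sulphate binding protein gene sbp, and cysN and cysD, for sulphate activation, were both at -2.05. Runs from PA3441 to PA3446 (6 loci, median -2.45, floored -1.48) and from tauD, for taurine dioxygenase, to PA3938 (4 loci, median -1.97, floored -1.65) were lower too, as was metY, of homocysteine synthesis, in a run of 3 (median -1.95). The histidine degradation genes hutH and hutU lay in a lower run of 7 loci from PA5095 to PA5101 (median -1.16, floored -1.02), and acoB, of acetoin degradation, in a lower run of 6 from PA4148 to PA4153 (median -1.42).

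On the higher side, the run from PA0429 to sahH (4 loci, median 2.38) held metF and the adenosylhomocysteinase gene sahH, whose enzyme releases adenosine and homocysteine; sahH went from 2903 to 16720, and metK, for S-adenosylmethionine synthetase, from 806 to 4875. Between PA2134 and PA2190, 26 of 48 loci that passed the filter were at least 2-fold higher and 0 lower (median 1.14, quartiles 0.70 and 1.58), within bounds drawn around loci seen to be higher; the catalase gene katE there was 6.34-fold higher. The glucose catabolism genes gapA (5.69-fold), pgl (3.32-fold), edd (2.99-fold) and zwf (2.02-fold), the periplasmic nitrate reductase genes napA (3.05-fold) and napB (3.27-fold), the formate dehydrogenase genes fdnG, fdnH and fdnI (median 1.86), the cytochrome bc1 loci from PA4429 to PA4431 (median 1.37) and the loci from PA0439 to dht (median 2.53, floored 1.49), of pyrimidine breakdown, were higher as well.

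All tests in the rest of this part were chosen after the results had been seen. The first pattern is the lower signal of the 75 iron uptake probe sets (median log2 ratio -1.88). Their median stayed at -1.45 or lower under the main setting and the 6 other scalings, filters and the pseudocount. The filters change no ratio, so they do not bear on scaling. Array scaling as the whole cause is argued against by the size of the shifts. These were 0.19 after median centring and 0.40 with control scaling, too small to give -1.88. A loss of weak signals on the adenosine array is argued against by the 39 members with a mean signal above that of the median probe set, whose median was -1.79. As a hypothesis, the Fur repressor may have been more active with adenosine, which would also lower the PrrF small RNAs and raise their targets: 11 of 11 such genes (sodB, bfrB, acnA, acnB, sdhA to sdhD and antA to antC) had a ratio above 1 (median 0.94) and 3 reached 2-fold, but 6 of the 11 are also in the TCA list, and antA and antB had been noticed before. The 3 others (sodB 1.56-fold, antC 1.36-fold, at least 1.22-fold, and bfrB 1.13-fold higher) had a median of 0.44 at percentile 96 of matched random lists, which is not apart, so the hypothesis stays open. A different growth stage of the adenosine culture cannot be told apart from adenosine itself with 1 array per medium and no time series. The ribosomal protein median of -0.04 does not settle it.

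The second pattern is the excess of lower over higher probe sets. In the dimmest 443 probe sets by mean signal the median log2 ratio was -0.46, with 119 lower and 7 higher, and in the brightest 443 it was 0.16, with 17 lower and 38 higher. After quantile normalization 47% of the changed probe sets were higher, against 32.2% as deposited, but median centring, a constant shift, gave 48.7%, and both scalings set the balance by construction. A signal-dependent difference between the arrays therefore cannot be told apart from a true excess of lower transcripts.

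The third pattern is the clustering of changed loci: 45 runs of 3 or more neighbouring measured loci changed at least 2-fold in 1 direction, 22 higher and 23 lower, holding 210 loci. Shuffling the loci 10000 times gave 1.62 runs on average and at most 8, so the one-sided permutation p was 0.0001, the smallest they can give. A chance order of the changed probe sets is argued against. The shuffle was not matched on signal, and members of an operon are not independent, so this p does not bear on adenosine as the cause. Shared operon transcription may account for the clustering, as may probe sets that respond alike to 1 hybridisation. Operon boundaries were not used here, so the former was not tested.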
